A study of Mus musculus with 15 samples.

How the data were processed

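RNA from the mouse auditory nerve was measured on 15 arrays, 3 in each of 5 groups: unexposed controls, and animals taken immediately, 1 day, 7 days or 14 days after noise. Per the labels, CBA/CaJ mice aged 5 to 12 weeks heard octave-band noise of 8 to 16 kHz at 106 dB SPL for 2 h, and each sample joined the tissue of both ears of a single animal. The cochlea was trimmed of its outer bone, lateral wall and most of the sensory epithelium, which left the modiolus with the nerve, and 50 ng of total RNA was labelled for each array. Each array is thus a separate animal. The tools named by the submitters' processing notes are Affymetrix Expression Console, RMA and MAS5, without versions.

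The deposited values were on the log2 scale, from 2.06 to 14.63, with none missing, which is the scale RMA gives. Which of RMA and MAS5 gave these values, and any further step of the authors, is not given in the sources used here. Array medians lay between 5.87 and 5.92, a range of 0.05, so the values were used without further normalization, and no pseudocount was needed. No pair of arrays shared more than 3.7% of identical values, so no sample was counted as a duplicate. Near background the signal compresses, so that changes of dim genes are understated. Array counts limit the precision here, with 3 arrays per group and 10 residual degrees of freedom.

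Gene names came from the platform annotation. Of 45101 probe sets, 34945 paired with 1 gene symbol, 932 with several and 9160 with none, and 64 were control probe sets. Gene IDs of 34741 of the 1-gene probe sets were found in the mouse gene table of assembly GRCm38.p6, and 0 symbols needed updating. The build behind the probe annotation is not given in the sources used here, so no coordinates are printed. Each of 18193 genes was represented by its 1-gene probe set with the highest mean over all arrays. Genes in the lowest 25% of mean value, at or below 4.70, were left out, and 13644 genes were tested.

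Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) over all 15 arrays, so that the groups shared an estimate of the spread. Tests were two-sided and adjusted by Benjamini-Hochberg within each of 7 contrasts: the 4 times against control and the 3 pairs of consecutive times. Adjusted p under 0.05 counted as a call, and a moderated F test covered any difference among the 5 groups. Errors beside log2 fold changes are standard errors of this fit. Control probe sets and those with several genes or none went through a separate fit of the same kind and were adjusted among themselves.

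The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined. Named genes against control were the 8 largest rises and 8 largest falls among calls whose 3 noise arrays all lay on the same side of the 3 controls. To these came the 2 largest called changes of each list with at least 3 called members, and 7 genes always named, of which 5 had a tested probe set and 2 were not analysed here. Where fewer than 3 genes were called in a direction, the 3 with the smallest p are given as values. Between consecutive times, the 5 largest called rises and 5 largest called falls were named. Xist, Tsix and Y-linked genes were left out of the first parts of the rule. Other genes named as members of a list or of an overlap were chosen after their values were seen.

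The 27 gene lists held 485 memberships, 39 of them without a 1-gene probe set. They were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast. An estimated correlation and fry were alternatives. With the estimated correlation 0 lists were called in any contrast, so every list call below rests on the preset value. No called list had a median, a mean and a test that differed in sign. Among lists not called against control, these differed for the node of Ranvier list at the immediate, 7-day and 14-day times, for the circadian and neutrophil lists immediately, for the glucocorticoid and skeletal muscle lists at 1 day, for organ of Corti support at 1 and 7 days, for endothelium at 7 days, for neurons at 14 days and for B cell genes, whose mean was 0.00, at 1 day.

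Sex was not balanced, since all 3 controls were female and all 3 arrays at 1 day were male. The same fit with sex as a term was therefore an alternative, and its values stand beside the counts, named genes and lists whose call it changed or whose value it moved by over 1.5 times. Further alternatives were no filter, a filter of the lowest 50%, the mean over probe sets, every probe set by itself, eBayes without the trend, robust eBayes, array weights, the replicate number as a block, only the 2 groups compared, quantile normalization, a common 75th percentile, each array left out, and an unadjusted threshold with a change of 1.5-fold. Female arrays alone and the simulated overlap of lists of the observed sizes were added after the data were seen. The functions were tested on simulated data for the comparison of 1 day with control over 13644 genes, of which 200 were changed. They recovered 65.1% of changes of 0.50, 94.9% of changes of 1.00 and 100% of changes of 2.00 on the log2 scale, and 5.4% of calls were false.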

Results

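Expression was measured in the auditory nerve of adult mice that heard loud noise and in unexposed controls. Each of the 5 groups held 3 animals, 9 females and 6 males in all. The series title names Quaking, an RNA-binding protein of myelinating cells, and the comparisons ask which transcripts differ from control at each time after noise and between consecutive times. Values are log2 intensities, differences are log2 fold changes with standard errors, and every group mean rests on n = 3 arrays. Xist and the Y-linked Eif2s3y matched the sex given for all 15 arrays. Xist lay between 11.88 and 12.07 in the 9 females and between 5.13 and 6.48 in the 6 males, and Eif2s3y between 3.15 and 4.33 in females and 9.14 and 9.61 in males. The female values of Eif2s3y give the level of an absent transcript for that probe set only. Male values of Xist lay higher, so the level near background can differ between probe sets. Genes kept by the filter can thus still lie near background, where sizes of change are uncertain.

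The 3' minus 5' difference of the beta-actin control sets was 0.54 ± 0.04 (SD, n = 3) in controls, and noise groups differed from it by -0.06 to -0.02. For Gapdh the control mean was -0.22 ± 0.04 (SD, n = 3), and noise groups differed by -0.06 to -0.03. Exact two-sided permutation p values ran from 0.2 to 0.4, where 3 arrays against 3 allow no p below 0.1. The 5' control set of 18S ribosomal RNA lay between 11.82 and 12.37 in controls, at or below 11.49 at 7 days, and between 11.30 and 11.67 at 14 days. At 7 days the 18S sets differed from control by -0.91 ± 0.13 at the 5' end (adjusted p = 0.0108), -1.13 ± 0.13 in the middle (adjusted p = 0.00114) and -0.30 ± 0.15 at the 3' end, which did not pass. At 14 days these differences were -0.64, -0.71 and -0.09, and none passed. The first principal component held 20.8% of the variance. The 3 arrays of 1 day lay at 13.8, 22.4 and 16.3 on it, while the other 12 arrays lay between -15.0, in 7-day replicate 2, and 3.1.

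Immediately after noise, activity-dependent transcription factors rose. Fos rose by 2.96 ± 0.43, Nr4a1 by 2.50 ± 0.23, Junb by 2.30 ± 0.42, Nr4a3 by 2.01 ± 0.28 and Fosl2 by 1.95 ± 0.30. Dio2, which activates thyroid hormone, rose by 2.35 ± 0.22, the GTPase gene Gem by 2.74 ± 0.36 and the cytokine-signalling inhibitor Socs3 by 1.97 ± 0.39. Fos went from 6.92 ± 0.35 (SD, n = 3) in controls to 9.87 ± 0.77 (SD, n = 3), and its adjusted p was 0.00480. The largest falls were smaller: Smpd3 (-0.93 ± 0.16), the prostaglandin-degrading enzyme gene Hpgd (-0.84 ± 0.14), Btla (-0.83 ± 0.17), Slc43a1 (-0.69 ± 0.12), Crtam (-0.64 ± 0.13), D930003E18Rik (-0.63 ± 0.14), Mxd4 (-0.60 ± 0.08) and Ccsap (-0.57 ± 0.12). The mean over all probe sets of a gene gave 0.70 for Nr4a3 and 0.97 for Fosl2, both still called. Control means of Gem (5.09), Socs3 (6.05) and Junb (6.19) lay under the highest male value of Xist, 6.48. Control and immediate means of Btla (5.79 and 4.96), Crtam (5.93 and 5.29), D930003E18Rik (5.93 and 5.3) and Ccsap (5.9 and 5.33) did so too. The sizes of these changes are therefore uncertain.

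**Figure D1:**
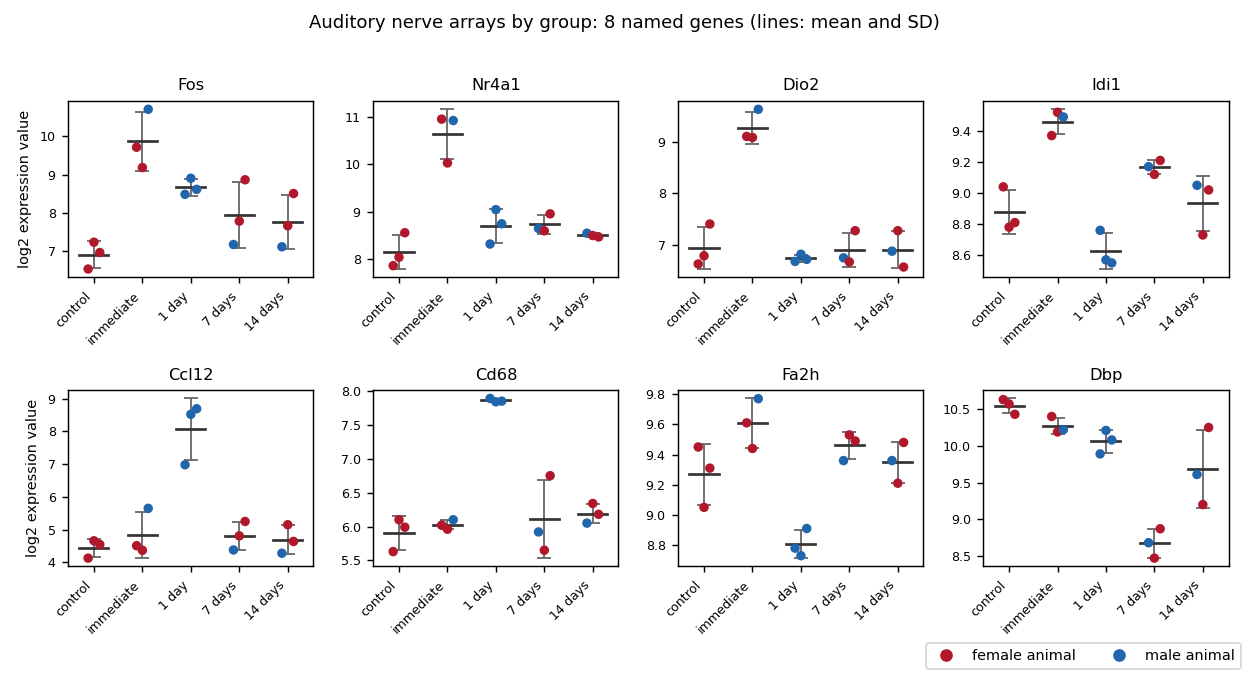
Each panel plots the log2 expression value of a named gene (y axis) for the 5 groups (x axis); points are arrays, coloured by the sex of the animal, and lines give the mean and SD of 3 arrays. Fos, Nr4a1 and Dio2 were highest immediately after noise, Ccl12 and Cd68 at 1 day (Cd68 7.86 against 5.91 in controls), and Dbp was lowest at 7 days, at 8.67.

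Among the lists, 20 immediate early genes were tested, and 6 rose over all genes and 16 adjusted over the list alone (camera adjusted p = 2.24e-18). With an estimated correlation the adjusted p = 0.0768. Of 20 genes of cholesterol synthesis, 5 rose over all genes and 10 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 8.19e-10; adjusted p = 0.0768 with an estimated correlation). Idi1 rose by 0.58 ± 0.09, Sqle by 0.47 ± 0.08 and Hmgcs1, which makes the precursor of mevalonate, by 0.40 ± 0.06. Heat shock genes had 1 of 14 called, and 5 adjusted over the list alone (median 0.19, camera adjusted p = 8.30e-06). Genes of the unfolded protein response had 1 of 17 called, and 4 adjusted over the list alone (median 0.20, camera adjusted p = 6.46e-06). For both lists the adjusted p = 0.459 with an estimated correlation.

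Cytokine and chemokine genes had 1 of 15 called immediately after noise, with 4 higher and 1 lower adjusted over the list alone (median 0.23, camera adjusted p = 0.0436; adjusted p = 0.680 with an estimated correlation). Oligodendrocyte genes had 0 of 16 called by either adjustment and a median of 0.21 (camera adjusted p = 0.0401; adjusted p = 0.803 with an estimated correlation). With sex as a term these 2 lists were not called, at adjusted p = 0.0761 and 0.119, nor with the lowest 50% of genes left out (median -0.16, adjusted p = 0.368, for cytokines, and adjusted p = 0.240 for oligodendrocytes). The cytokine median was 0.10 with every probe set by itself (0.0819) or in female arrays (0.113), where it was not called, and 0.11 without the filter, and the call also ended in a fit to the 2 groups (0.0520). The bone list, a marker of tissue around the nerve, had 0 of 8 called and 3 lower adjusted over the list alone (median -0.36, camera adjusted p = 0.0355; adjusted p = 0.798 with an estimated correlation). It was not called with the lowest 50% left out (0.0525), as the mean over probe sets (0.0594), with every probe set by itself (0.0623) or with array weights (0.0605).

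In all, 79 genes rose and 48 fell immediately after noise, 0.93% of 13644, and 16 rises but 0 falls reached 2-fold. With sex as a term 52 rose and 27 fell, 68 of them among the calls without it, and Socs3 (adjusted p = 0.0553), Crtam (0.0616), D930003E18Rik (0.0502) and Ccsap (0.0592) were not called. The total of 127 was lower without each of the 6 arrays in turn: it was 80, 35 and 57 without control replicate 1, 2 or 3, and 69, 65 and 29 without immediate replicate 1, 2 or 3. Quantile normalization gave 87 rises and 83 falls, and a common 75th percentile 82 and 76. Array weights gave 397 rises and 360 falls, with all 127 calls among them, and every probe set by itself gave 246 genes. Female arrays alone, a choice made after the data were seen, gave 6 rises and 2 falls.

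Several of these calls ended with an array fewer, while the changes kept their direction. Over all 15 arrays left out in turn, Junb ranged from 1.86 to 2.96, Socs3 from 1.38 to 2.39, Btla from -1.09 to -0.67, Smpd3 from -1.09 to -0.70, Slc43a1 from -0.78 to -0.64, Crtam from -0.70 to -0.57, D930003E18Rik from -0.69 to -0.54, Ccsap from -0.62 to -0.54, Idi1 from 0.54 to 0.67 and Sqle from 0.41 to 0.54. Crtam (adjusted p up to 0.112), D930003E18Rik (up to 0.171) and Ccsap (up to 0.140) were not called without any single control or immediate array. Junb (up to 0.112) and Socs3 (up to 0.0985) were called without immediate replicate 2 but not without any of the other 5 arrays. Btla was called without immediate replicate 3 but not without any of the other 5 (up to 0.149). Arrays outside this comparison, which enter through the shared spread, also ended calls: Btla and D930003E18Rik without 1-day replicate 3 or 14-day replicate 1, and Ccsap without 1-day replicate 3 or 14-day replicate 2 (adjusted p from 0.0506 to 0.0538). Slc43a1 was not called without control replicate 2 (0.0723) or immediate replicate 1 (0.0517) or 3 (0.0682), and Smpd3 not without immediate replicate 2 (0.0608). Idi1 (0.0506 and 0.0503) and Sqle (0.0577 and 0.0682) were not called without control replicate 2 or immediate replicate 3. The bone list was not called without control replicate 3 (median -0.03, adjusted p = 0.692) or immediate replicate 1 (0.294) or 2 (0.0816), and the oligodendrocyte list not without control replicate 3 (median 0.05, adjusted p = 0.922) or immediate replicate 2 (median 0.13, adjusted p = 0.535), while its median was 0.33 without control replicate 1. Without control replicate 1 or immediate replicate 3 the cytokine list was not called (0.159 and 0.165, the latter with a median of 0.10), nor without any 7-day array or 14-day replicate 3 (0.0515 to 0.0632).

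At 1 day after noise, chemokine and macrophage genes rose. The chemokine Ccl12 rose by 3.62 ± 0.41, from a control mean of 4.45 that lay under the filter level of 4.70, and Cxcl10 by 2.31 ± 0.32. Cd68, a lysosomal protein of macrophages, rose by 1.95 ± 0.20, Ms4a6d by 1.68 ± 0.22 and Cd52 by 1.43 ± 0.25. The neuropeptide precursor Vgf rose by 2.91 ± 0.34, the stress-response gene Gadd45a by 1.84 ± 0.23, Atf3 by 1.64 ± 0.27, Socs3 by 2.01 ± 0.39 and Fos by 1.76 ± 0.43. Vgf, at 4.60 in controls, stood at 7.50 ± 0.08 (SD, n = 3), with an adjusted p of 0.000876. Control means of Cxcl10 (4.24) and Ms4a6d (4.36) also lay under the filter level, near the highest Eif2s3y value of females, so the sizes of these 4 rises are uncertain.

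Of 26 macrophage genes tested at 1 day, 10 rose and 0 fell over all genes, while 16 were higher and 1 lower adjusted over the list alone (median 0.51, camera adjusted p = 4.48e-15; adjusted p = 0.273 with an estimated correlation). The list's rises included Ly86 (1.24 ± 0.13), Aif1 (1.33 ± 0.18) and the complement subunit C1qb (1.14 ± 0.16). Cytokine and chemokine genes had 6 of 15 called, all rises (median 0.17, mean 0.79, camera adjusted p = 0.000136; adjusted p = 0.273 with an estimated correlation), and 6 adjusted over the list alone. With the lowest 50% of genes left out the cytokine list was not called and its median was -0.07 (adjusted p = 0.659). That median was 0.09 without the filter, 0.47 as the mean over probe sets and 0.08 with array weights, and 0.07 without control replicate 1, 0.06 without 1-day replicate 1 and 0.27 without 1-day replicate 2. Interferon response genes had a median of 1.09 with 1 of 18 called, Gbp2, and 8 adjusted over the list alone (camera adjusted p = 7.45e-08; adjusted p = 0.358 with an estimated correlation). Immediate early genes had 3 of 20 called, all rises, and 7 adjusted over the list alone (median 0.44, camera adjusted p = 1.22e-07; adjusted p = 0.358 with an estimated correlation), and a median of 0.28 with sex as a term.

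Smaller rises at 1 day came in 3 further lists. Antioxidant response genes had 2 of 12 called and 3 adjusted over the list alone (median 0.19, camera adjusted p = 0.000425; adjusted p = 0.273 with an estimated correlation), with sulfiredoxin Srxn1 up by 0.58 ± 0.05. The antioxidant median was 0.07 without control replicate 3. Cell cycle genes had 1 of 15 called and 4 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.000621; adjusted p = 0.358 with an estimated correlation). These 4 were Mcm4, which was also called over all genes, Mcm5, Mcm6 and Pcna, all of DNA replication, and the list's median was 0.14 without control replicate 1. For the unfolded protein response 2 of 17 were called, Asns and Chac1, and 2 adjusted over the list alone (median 0.09, camera adjusted p = 0.00453; adjusted p = 0.446 with an estimated correlation). With the sex term that median was 0.29 (adjusted p = 1.93e-08).

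Myelin, lipid and neuronal lists were lower at 1 day. Of 18 genes of peripheral myelin and Schwann cells, 4 fell and 0 rose over all genes, and 6 were lower adjusted over the list alone (median -0.04, mean -0.10, camera adjusted p = 0.00573; adjusted p = 0.366 with an estimated correlation). Fa2h, which makes hydroxylated myelin lipids, fell by 0.46 ± 0.10, Ncmap, a protein of noncompact myelin, by 0.32 ± 0.07, and the myelin enzyme gene Cnp by 0.24 ± 0.04. The myelin median was -0.12 without control replicate 3, -0.11 without 1-day replicate 3, -0.08 without control replicate 1 and -0.02 without control replicate 2 or 1-day replicate 1 or with every probe set by itself. Cholesterol synthesis had 2 of 20 lower and 5 adjusted over the list alone (median -0.12, or -0.07 without control replicate 1, camera adjusted p = 0.00465; adjusted p = 0.358 with an estimated correlation). Of 24 spiral ganglion neuron genes, Calb2 fell and Uchl1 rose, and 7 were lower and 2 higher adjusted over the list alone (median -0.14, camera adjusted p = 0.0266; adjusted p = 0.538 with an estimated correlation), and the neuron list was not called without the eBayes trend (0.0613).

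Bone markers were also lower at 1 day. The bone list had 3 of 8 called, all falls, and 6 adjusted over the list alone (median -0.80, camera adjusted p = 0.000144; adjusted p = 0.358 with an estimated correlation). Ibsp fell by 1.72 ± 0.43 and Dmp1 by 0.81 ± 0.19, both proteins of mineralized matrix. The other large falls at 1 day were Hpgd (-1.06 ± 0.14), the muscle gene Ttn (-1.05 ± 0.24), Ucma (-1.05 ± 0.13), a cartilage matrix gene, Thap2 (-0.96 ± 0.18), the tendon gene Tnmd (-0.94 ± 0.13), Sfi1 (-0.92 ± 0.13) and Btla (-0.90 ± 0.17). The mean over all probe sets of a gene gave -0.45 for Ttn, which was then not called (adjusted p = 0.0729), and -0.49 for Thap2 and -0.51 for Sfi1, both called. The bone median was -0.49 without control replicate 3 and -0.42 without the filter.

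At 1 day 207 genes rose and 227 fell against control, 3.18% of 13644, with 25 rises and 4 falls of at least 2-fold. Controls were all female and the 1-day animals all male, and with sex as a term 38 rose and 37 fell, 67 of them among the calls without it. All 434 called genes kept their direction, and their median change in that direction was 0.42 without and 0.43 with the term, while the median standard error of all genes went from 0.097 to 0.129. Calls of Socs3 (adjusted p = 0.138), Fos (0.114), Cd52 (0.0729), Ibsp (0.148), Dmp1 (0.0822), Thap2 (0.0822), Sfi1 (0.0694), Fa2h (0.123) and Ncmap (0.0996) ended there. The count was 241, 231 and 125 without control replicate 1, 2 or 3, and 112 and 186 without 1-day replicate 2 or 3. Array weights gave 1106, with all 434 among them, and an unadjusted p under 0.05 with 1.5-fold gave 195.

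Of the genes named at 1 day, Fos (adjusted p up to 0.153) and Ttn (up to 0.123) were not called without any single control or 1-day array, and Fos also not without immediate replicate 1 (0.0548). Ibsp was not called without control replicate 3 (-1.14, adjusted p = 0.155) or any single 1-day array (up to 0.119), nor without immediate replicate 2 or 14-day replicate 2 or 3 (0.0507 to 0.0557). Dmp1 was not called without control replicate 1 (0.0520) or 3 (0.149) or any single 1-day array (up to 0.0920). Without control replicate 3 or 1-day replicate 2, Socs3 (0.0594 and 0.0794), Thap2 (0.0582 and 0.0648) and Btla (0.0684 and 0.0803) were not called. Fa2h was not called without control replicate 1 (0.0970) or 3 (0.108) or 1-day replicate 1 (0.0593) or 2 (0.130), and Ncmap not without control replicate 1 (0.106) or 3 (0.0818) or 1-day replicate 2 (0.153) or 3 (0.104). Their changes kept direction over the 15 arrays left out: Fos ranged from 1.57 to 1.92, Ttn from -1.15 to -0.99, Ibsp from -2.03 to -1.14, Dmp1 from -0.92 to -0.62, Socs3 from 1.76 to 2.16, Thap2 from -1.18 to -0.82, Btla from -0.96 to -0.80, Fa2h from -0.57 to -0.37 and Ncmap from -0.38 to -0.25. The myelin list was not called without 1-day replicate 1 (adjusted p = 0.0774), nor the neuron list without control replicate 3 (0.0672) or 1-day replicate 2 (0.0861).

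At 7 days after noise the clearest differences were in clock-controlled genes. Dbp, a transcription factor driven by the circadian clock, fell by 1.87 ± 0.19 (adjusted p = 0.000775), from 10.54 to 8.67, and Ciart, a repressor within the clock, by 1.18 ± 0.13 (adjusted p = 0.00107). At 14 days they differed from control by -0.86 ± 0.19 and -0.57 ± 0.13, which did not pass. From 1 to 7 days Dbp changed by -1.39 ± 0.19 (adjusted p = 0.00114) and Ciart by -1.26 ± 0.13 (adjusted p = 0.000556), so both were lower at 7 days than at 1 day. The change from 7 to 14 days passed for neither, so their fall was not shown to be particular to 7 days as against 14 days. The long noncoding RNA Neat1 rose by 0.75 ± 0.11 (adjusted p = 0.0466), which was not called with sex as a term (adjusted p = 0.0652) nor as the mean over its 2 probe sets (0.16, adjusted p = 0.628). The 18S ribosomal RNA sets at the 5' end (-0.91) and in the middle (-1.13) were lower on the same arrays. Dbp, Ciart and Neat1 were the only 3 calls with limma among 13644 genes, where 1525 had an unadjusted p under 0.05. Next by p in each direction came Shh (0.64 ± 0.10) and Uchl1 (0.42 ± 0.08) upward and Slc9a3r1 (-0.32 ± 0.05) downward, none of which passed. Of 14 circadian clock genes 2 fell over all genes, and 5 were lower and 1 higher adjusted over the list alone (median -0.14, camera adjusted p = 0.00128; adjusted p = 0.265 with an estimated correlation). The list also holds Arntl, Npas2 and Clock, of the opposite clock phase to Dbp and Ciart, so opposite changes can cancel in its median and test. Without control replicate 3 the count of calls was 5, and without 7-day replicate 1 it was 50. The circadian median was -0.08 without 7-day replicate 1 and -0.22 without 7-day replicate 3, -0.22 as the mean over probe sets, -0.09 with array weights and -0.08 in female arrays. Every probe set by itself gave 16 calls, the lowest 50% left out 7, and a fit to the 2 groups alone 1. Ciart was not called in a fit to the 2 groups alone (adjusted p = 0.0697), nor Dbp in female arrays alone (0.0590), and Neat1 was lost without control replicate 1 (0.144) or 2 (0.240) or 7-day replicate 2 (0.0962) or 3 (0.203). Neat1 ranged from 0.67 to 0.82 with each array left out, and was also lost without immediate replicate 2, 1-day replicate 2 or 3, or 14-day replicate 1 or 3 (0.0556 to 0.0842), while Shh was called without control replicate 3 (0.0292) or 7-day replicate 1 (0.0206), and Slc9a3r1 without the latter (0.0465).

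Other lists called at 7 days held 0 members called over all genes. Peripheral myelin and Schwann cell genes had a median of 0.09 and 2 members higher adjusted over the list alone, Gjb1 and Dhh (camera adjusted p = 0.0195), and cholesterol synthesis a median of 0.08 with 4 higher (camera adjusted p = 0.0195). Immediate early genes (0.17, adjusted p = 0.0242), heat shock genes (0.10, 0.0195), the unfolded protein response (0.09, 0.0429) and interferon response genes (0.32, 0.0280) had medians above 0. The glucocorticoid response (-0.19), cell cycle (-0.16), neutrophil and myeloid precursor (-0.85) and erythroid (-0.44) lists had medians below 0, each at camera adjusted p = 0.0195, and bone genes (-0.39) at 0.00315. With an estimated correlation the interferon list had an adjusted p = 0.786, and each of the others named here had an adjusted p = 0.669. When sex was a term, cholesterol synthesis (adjusted p = 0.0503), immediate early (0.165) and cell cycle genes (0.0503) were not called, and the median of the unfolded protein response was 0.16 (0.00152). Without control replicate 3, 4 lists were called in place of 12: the neutrophil median was 0.09, that of erythroid genes -0.08, of bone genes -0.15 and of cell cycle genes -0.03. The neutrophil (-1.44) and glucocorticoid (-0.11) medians moved without control replicate 1, and those of cell cycle genes (-0.26) and cholesterol synthesis (0.05) without control replicate 2. Without 7-day replicate 2 the medians of immediate early genes and myelin were 0.33 and 0.04. The unfolded protein response had 0.16 without 7-day replicate 1, and -0.03 without 7-day replicate 3, where immediate early genes had 0.08. With the lowest 50% of genes left out the glucocorticoid (0.0862), interferon (0.101), cell cycle (median -0.06, adjusted p = 0.863) and neutrophil lists (-1.03, 0.379) were not called. Without the filter the neutrophil and bone medians were -0.52 and -0.22. Every probe set by itself gave -0.12 for the glucocorticoid list and ended the calls of immediate early genes (0.05, 0.0734) and the unfolded protein response (0.01, 0.121). The latter was also not called as the mean over probe sets (0.06, 0.138), in a fit to the 2 groups (0.0573), with quantile normalization (0.0525) or without the eBayes trend (0.0578), and had 0.16 in female arrays. Those arrays ended the calls of cholesterol synthesis and interferon genes (both 0.0704), cell cycle and erythroid genes (both 0.170), neutrophil (0.172) and bone genes (0.0558). The glucocorticoid list was not called without 7-day replicate 2 (median -0.11, adjusted p = 0.601), and the myelin list not without that array (0.294) or control replicate 3 (0.105). Cell cycle (0.153), neutrophil (0.179) and erythroid genes (0.158) were not called without 7-day replicate 1, and cholesterol synthesis not without control replicate 2 (0.0946). Immediate early genes were not called without control replicate 1 (0.113) or 7-day replicate 3 (0.244), and heat shock genes not without control replicate 3 (0.0698) or 7-day replicate 3 (0.146). The interferon list was not called without control replicate 2 or 3 or any 7-day array (up to 0.0942), and the unfolded protein response not without any control array, immediate replicate 1, or 7-day replicate 2 or 3 (up to 0.765).

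At 14 days 0 genes passed with limma, where 1071 of 13644 had an unadjusted p under 0.05 and 58 of these changed at least 1.5-fold. The smallest p values upward belonged to Ceacam10 (0.83 ± 0.13, adjusted p = 0.282), Tns3 (0.26 ± 0.05) and Fut9 (1.02 ± 0.19), and downward to Slc43a1 (-0.67 ± 0.12), Zbed6 (-0.61 ± 0.12) and Pdap1 (-0.34 ± 0.07). Without 14-day replicate 3, 1 gene was called, and array weights also called 1. Of the lists, neutrophil and myeloid precursor genes had the lowest median, -1.22 (camera adjusted p = 1.91e-06; adjusted p = 0.473 with an estimated correlation), with 4 of 8 lower adjusted over the list alone. That median was -0.68 without the filter on dim genes, -2.46 with the lowest 50% of genes left out and -0.40 without control replicate 3, where the bone median was -0.23. Interferon response genes had a median of 0.59 (camera adjusted p = 1.91e-06; adjusted p = 0.487 with an estimated correlation). That call was lost without 14-day replicate 2, where the median was 0.12.

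Bone genes had a median of -0.43 at 14 days (camera adjusted p = 1.07e-05), erythroid genes of -0.49 (0.00272) and circadian clock genes of -0.02 (0.0367), while heat shock genes had a median of 0.18 (3.40e-05). With an estimated correlation each of these 4 lists had an adjusted p = 0.473. Glucocorticoid response genes had a median of -0.15 (camera adjusted p = 0.00210), cell cycle genes of -0.13 and extracellular matrix genes of -0.05 (both 0.00288), each with an adjusted p = 0.487 with an estimated correlation. When sex was a term, the extracellular matrix (adjusted p = 0.0506) and circadian (0.20) lists were not called, each with a median of 0.01, and the glucocorticoid median was -0.30 (4.98e-06). The unfolded protein response was called only with that term, with a median of 0.12 (adjusted p = 0.00157) against 0.08 (0.112) without it. Without control replicate 3 the erythroid (median -0.10, adjusted p = 0.402), cell cycle (-0.01, 0.792) and extracellular matrix lists (0.01, 0.273) were not called, nor the circadian list without 14-day replicate 1 (0.03, 0.302), control replicate 2 (0.161) or 7-day replicate 1 (0.0671) or 2 (0.0562), nor the extracellular matrix list without 14-day replicate 1 (-0.03, 0.0939), nor the glucocorticoid list without 14-day replicate 3 (-0.06, 0.0645). The heat shock median was 0.28 without 14-day replicate 1 and 0.08 without 14-day replicate 3, and the glucocorticoid median -0.26 without 14-day replicate 1. Circadian genes had -0.07 without control replicate 3 and -0.12 without 14-day replicate 3, and extracellular matrix genes -0.11 without control replicate 1 or 14-day replicate 2 and -0.01 without 14-day replicate 3. Without the filter the bone median was -0.13. The circadian list was also not called as the mean over probe sets (-0.01, 0.0564), with every probe set by itself (0.0501), array weights (0.0560), a fit to the 2 groups (0.0975), quantile normalization (0.0550), a common 75th percentile (-0.04, 0.0724), no eBayes trend (0.0509) or the replicate block (0.0607), nor in female arrays (0.03, 0.441), where the extracellular matrix list was lost too (-0.03, 0.0845). With the lowest 50% left out the cell cycle list was not called (-0.01, 0.873), the circadian median was -0.06, the extracellular matrix median -0.01 and the glucocorticoid median -0.09, and the last was also -0.09 as the mean over probe sets or with every probe set by itself. Extracellular matrix genes had -0.09 in both of these and -0.08 with array weights, and heat shock genes 0.11 with every probe set by itself. In female arrays heat shock genes had 0.28 and the glucocorticoid list -0.26. Adjusted over the list alone, 5 heat shock genes were higher, and 4 bone, 4 clock and 2 extracellular matrix genes lower.

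**Figure D2:**
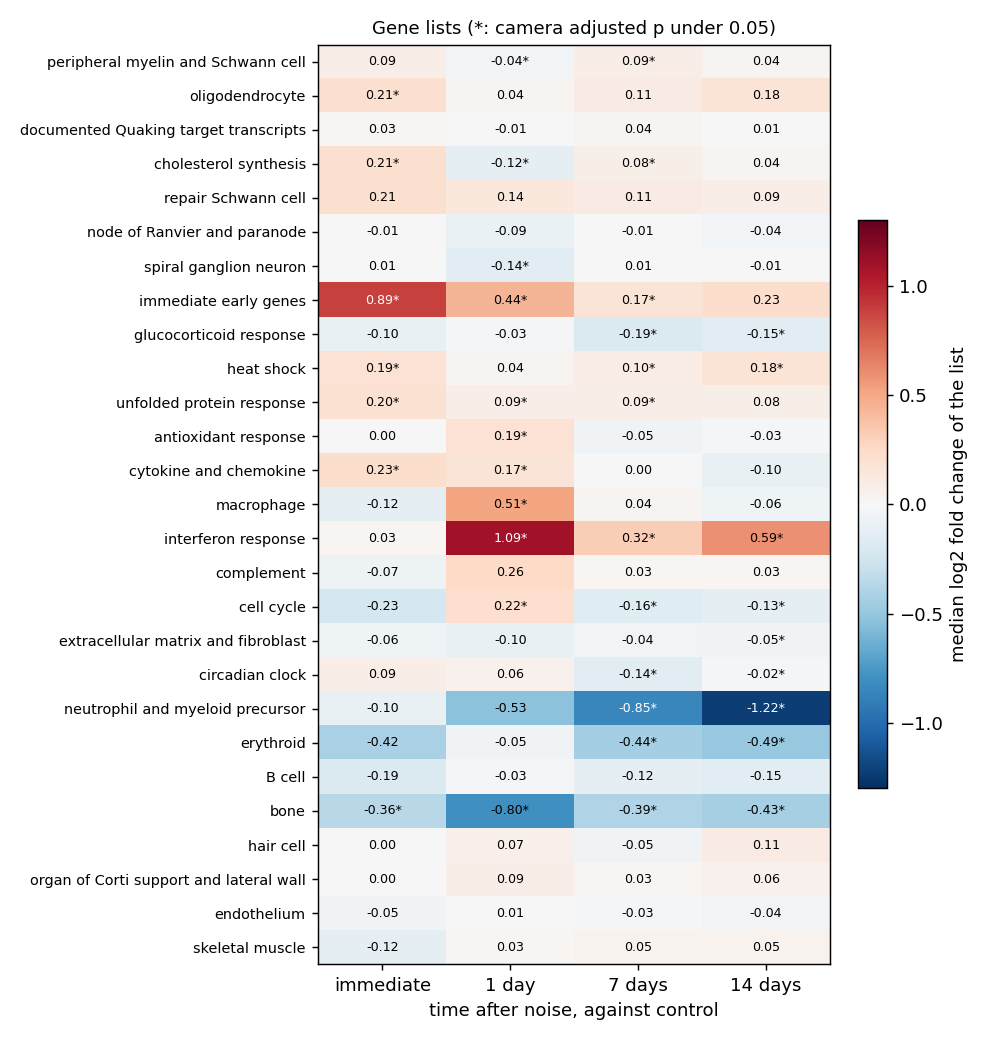
Rows are the 27 gene lists and columns the 4 times after noise against control; colour and number give the median log2 fold change of the list, and a star a camera adjusted p under 0.05 at the preset correlation. Immediate early genes stood highest immediately after noise (0.89), interferon response genes at 1 day (1.09), and neutrophil genes lowest at 14 days (-1.22).

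Some lists were not called at any time against control, though single members of some of these lists were. The documented Quaking target transcripts had medians of 0.03, -0.01, 0.04 and 0.01 from the immediate group to 14 days. Of these 11 genes, 1 fell at 1 day, Cnp, over all genes and adjusted over the list alone. Repair Schwann cell genes had medians of 0.21, 0.14, 0.11 and 0.09, and Shh rose immediately by 0.49 ± 0.10, though not with sex as a term (adjusted p = 0.0533). Genes of the node of Ranvier and paranode had medians of -0.01, -0.09, -0.01 and -0.04, and the scaffold genes Ank2 (-0.41 ± 0.07) and Ank3 (-0.26 ± 0.06) fell at 1 day, neither of them with sex as a term (adjusted p = 0.0658 and 0.0563). Complement genes had medians of -0.07, 0.26, 0.03 and 0.03, hair cell genes 0.00, 0.07, -0.05 and 0.11, and B cell genes -0.19, -0.03, -0.12 and -0.15. For organ of Corti support and lateral wall the medians were 0.00, 0.09, 0.03 and 0.06, with a fall of Otos, a fibrocyte gene, at 1 day (-0.51 ± 0.06), for endothelium -0.05, 0.01, -0.03 and -0.04, and for skeletal muscle -0.12, 0.03, 0.05 and 0.05. At 1 day 4 lists passed only with sex as a term. With it the node of Ranvier list was lower (median -0.15, adjusted p = 0.0104), and heat shock (0.14, 0.00338) and complement genes (0.38, 0.0141) higher, where the medians without it were -0.09, 0.04 and 0.26. The glucocorticoid response was lower with the term (median -0.33, adjusted p = 0.0194), while without it the median was -0.03 and the mean 0.04.

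Quaking, listed as Qk, was read by 7 probe sets, tested among all 34945 1-gene probe sets, and they did not move together. Probe set 1425597_a_at rose by 0.47 ± 0.09 immediately after noise (adjusted p = 0.0292), from 7.92 ± 0.15 to 8.40 ± 0.15 (SD, n = 3). Probe set 1451179_a_at rose by 0.37 ± 0.06 at 1 day (adjusted p = 0.00820), from 10.64 ± 0.07 to 11.01 ± 0.10 (SD, n = 3). Neither was called with sex as a term, at 0.42 (adjusted p = 0.0553) and 0.28 (adjusted p = 0.162). The brightest probe set, 1429318_a_at, differed from control by -0.07 ± 0.07, 0.12 ± 0.07, -0.04 ± 0.07 and 0.00 ± 0.07 at the 4 times, so the other sets that rose did so without it. At 7 and 14 days 0 of the 7 probe sets passed, and which isoform each probe set reads was not analysed here.

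Leaving out single arrays ended both Qk calls. Probe set 1425597_a_at had an adjusted p of 0.0686 and 0.136 without control replicate 2 or 3, and 0.0629 and 0.194 without immediate replicate 1 or 3. For 1451179_a_at it was 0.0562 without control replicate 3 and 0.0651 without 1-day replicate 2.

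**Figure D3:**
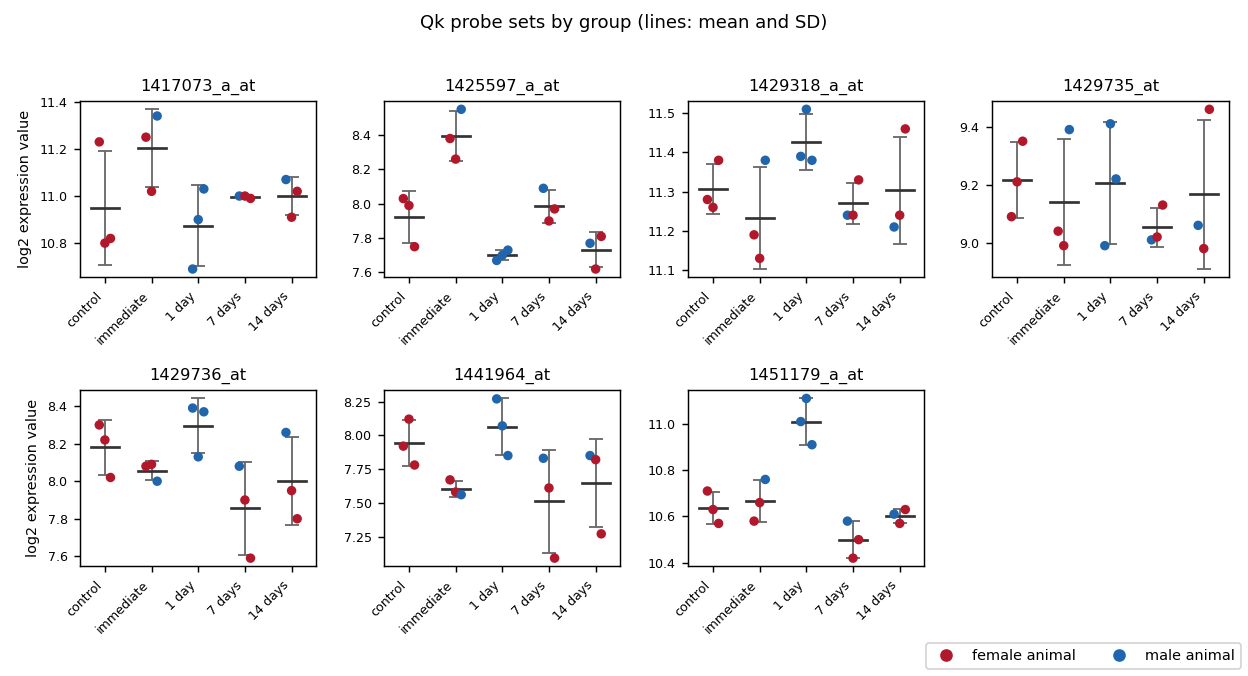
Each panel plots the log2 value of a Qk probe set (y axis) for the 5 groups (x axis); points are arrays coloured by the sex of the animal, and lines give the mean and SD of 3 arrays. Probe set 1425597_a_at was highest immediately after noise (8.40) and 1451179_a_at at 1 day (11.01).

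The myelin genes always named did not pass against control at any time. Mbp differed by 0.05 ± 0.05, 0.00 ± 0.05, 0.02 ± 0.05 and 0.01 ± 0.05 from the immediate group to 14 days. Mag, a myelin adhesion protein gene, differed by -0.03, -0.01, 0.24 and 0.25, each ± 0.15, Pmp22 by -0.12, -0.09, -0.02 and -0.07, each ± 0.04, and Egr2, a regulator of myelination, by 0.44, -0.01, 0.37 and 0.31, each ± 0.14.

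Between the immediate group and 1 day, 548 genes rose and 597 fell. Ccl12 (3.22 ± 0.41), Vgf (2.29 ± 0.34), Cd68 (1.83 ± 0.20), Cd52 (1.56 ± 0.25) and Cxcl10 (1.5 ± 0.32) rose most, while Dio2 (-2.55 ± 0.22), Gem (-2.44 ± 0.36), Nr4a1 (-1.94 ± 0.23), Nr4a3 (-1.87 ± 0.28) and the vitamin D receptor gene Vdr (-1.20 ± 0.20) fell most. Cholesterol synthesis genes turned from higher to lower, with 11 of 20 falling (camera adjusted p = 4.98e-11; adjusted p = 0.0529 with an estimated correlation), and 14 of 26 macrophage genes rose (camera adjusted p = 1.42e-14; adjusted p = 0.299 with an estimated correlation). The mean over all probe sets gave -0.69 for Nr4a3, still called. The fit with sex as a term gave 254 rises and 398 falls. Cxcl10 was not called without immediate replicate 1 (adjusted p = 0.0505) or 3 (0.0501) or 1-day replicate 2 (0.0546). The total of 1145 was 706, 706 and 382 without immediate replicate 1, 2 or 3, and 744, 442 and 553 without 1-day replicate 1, 2 or 3. Array weights gave 1898, and an unadjusted p under 0.05 with 1.5-fold gave 271. The 18S ribosomal RNA set at the 5' end differed by -0.60 ± 0.13 between these groups (adjusted p = 0.0264).

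From 1 day to 7 days 700 genes rose and 576 fell. Ccl12 (-3.25 ± 0.41), Socs3 (-2.14 ± 0.39), Cxcl10 (-2.04 ± 0.32), the prostaglandin synthase gene Ptgs2 (-1.83 ± 0.49) and Coro1a (-1.77 ± 0.29), of leukocytes, fell most. Rises were led by Thap2 (1.27 ± 0.18), Sfi1 (1.22 ± 0.13), Zfp82 (1.16 ± 0.18), 9530059O14Rik (1.04 ± 0.13) and Kbtbd8 (1.02 ± 0.30). Zfp82 (4.53) and Kbtbd8 (4.65) at 1 day and Cxcl10 (4.51) and Ptgs2 (4.10) at 7 days had means under the filter level of 4.70, so the sizes of these changes are uncertain. The mean over all probe sets gave 0.61 for Thap2, 0.61 for Sfi1, 0.55 for 9530059O14Rik and -1.08 for Coro1a, all called. Peripheral myelin and Schwann cell genes had 5 of 18 rising (median 0.25, camera adjusted p = 2.15e-05; adjusted p = 0.189 with an estimated correlation), and 13 of 26 macrophage genes fell (median -0.52, camera adjusted p = 1.87e-10; adjusted p = 0.189 with an estimated correlation). With sex as a term 272 rose and 177 fell, and Ptgs2 (-1.20, adjusted p = 0.171) and Kbtbd8 (0.0585) were not called. Ptgs2 was also lost without 1-day replicate 2 (0.138) or 3 (0.0563) or 7-day replicate 2 (0.0996) or 3 (0.0537), and Kbtbd8 without control replicate 3, any immediate array, 1-day replicate 2 or 3, 7-day replicate 1 or 2, or 14-day replicate 1 (0.0546 to 0.162). The total of 1276 was 429 and 736 without 1-day replicate 2 or 3, and 724 without 7-day replicate 2. A fit to these 2 groups alone gave 200, array weights 710, and an unadjusted p under 0.05 with 1.5-fold 222. The 18S sets at the 5' end (-0.83, adjusted p = 0.00525) and in the middle (-0.89, adjusted p = 0.00321) were lower at 7 days than at 1 day. With each array left out Ptgs2 ranged from -2.04 to -1.48 and Kbtbd8 from 0.74 to 1.38.

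Between 7 and 14 days 0 genes passed with limma, where 286 had an unadjusted p under 0.05 and 682.2 would be expected by chance, and 1 passed without 14-day replicate 2. Over the 5 groups together, 921 genes differed by the F test, and 435 with sex as a term. That count was 478 without immediate replicate 3 and 307 and 408 without 1-day replicate 2 or 3, 1798 with array weights and 1679 with every probe set by itself.

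Calls immediately after noise and at 1 day overlapped by 16 rises and 7 falls. Shared rises included Fos, Socs3, Hbegf, Osmr and Tgfbi, and shared falls Hpgd, Acan and Smpd3, of which Hbegf, Osmr, Tgfbi and Acan were chosen after their values were seen. Independent lists of these sizes would share 1.2 rises and 0.8 falls. In 50 simulations of unchanged groups against the same controls, lists of the same sizes, taken in order of p, shared 14 to 31 rises (mean 22.1) and 9 to 28 falls (mean 16.6). The observed overlap was not above these ranges, and the 7 falls lay below theirs. No gene changed in the simulations, so their lists were ranked by noise alone, while the observed lists were calls. They therefore cannot tell how much of the observed overlap the shared controls gave, and the 3 control arrays were too few to split. The sum of 23 was 5 with sex as a term and 128 with array weights. It was 13, 5 and 5 without control replicate 1, 2 or 3, 8, 13 and 9 without immediate replicate 1, 2 or 3, 6 and 12 without 1-day replicate 2 or 3, and 13 without 14-day replicate 1.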

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

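The tests of RNA quality, the last of 4 tried, and of a lower share of all non-neural cells, the last of 2, were chosen only after the results they bear on were seen.

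Many results differed between times by a test of the difference itself. Between the immediate group and 1 day 1145 genes differed, and between 1 and 7 days 1276. From the immediate group to 1 day the log2 changes were 3.22 for Ccl12, 2.29 for Vgf, 1.83 for Cd68, 1.56 for Cd52, 1.5 for Cxcl10, -2.55 for Dio2, -2.44 for Gem, -1.94 for Nr4a1, -1.87 for Nr4a3 and -1.20 for Vdr. From 1 to 7 days they were 1.27 for Thap2, 1.22 for Sfi1, 1.16 for Zfp82, 1.04 for 9530059O14Rik, 1.02 for Kbtbd8, -3.25 for Ccl12, -2.14 for Socs3, -2.04 for Cxcl10, -1.83 for Ptgs2 and -1.77 for Coro1a. For Qk, probe set 1425597_a_at differed by -0.70 and 1451179_a_at by 0.34 between the immediate group and 1 day, and 1451179_a_at by -0.51 between 1 and 7 days.

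Gene lists also differed between consecutive times at the preset correlation. With an estimated correlation none did: the adjusted p ran from 0.0529 to 0.516 for 1 day against the immediate group, from 0.163 to 0.673 for 7 days against 1 day and from 0.217 to 0.788 for 14 days against 7 days. From the immediate group to 1 day the medians were -0.18 for peripheral myelin, -0.33 for cholesterol synthesis, -0.13 for the node of Ranvier, -0.13 for spiral ganglion neurons, -0.43 for immediate early genes and -0.14 for heat shock. They were 0.19 for the antioxidant response, 0.57 for macrophages, 0.90 for the interferon response, 0.30 for complement and 0.34 for the cell cycle. From 1 to 7 days they were 0.25 for peripheral myelin, 0.19 for cholesterol synthesis, 0.17 for the node of Ranvier, 0.14 for neurons, -0.33 for immediate early genes, -0.29 for the glucocorticoid response and -0.18 for the antioxidant response. Over the same interval they were -0.17 for cytokines, -0.52 for macrophages, -0.72 for the interferon response, -0.35 for the cell cycle and -0.19 for the circadian clock. From 7 to 14 days they were -0.05 for peripheral myelin, -0.06 for cholesterol synthesis, -0.07 for macrophages, 0.31 for the interferon response, 0.12 for the circadian clock and -0.42 for neutrophils.

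Some of these list calls ended without single arrays or with sex as a term. For 1 day against the immediate group these were immediate early genes without immediate replicate 3 (median -0.21, adjusted p = 0.165), complement without immediate replicate 1 or 2 or 1-day replicate 3 (up to 0.0926), and heat shock with sex as a term (-0.05, 0.202). For 7 days against 1 day they were the node of Ranvier without 1-day replicate 1 or 3 or 7-day replicate 1 or 2 (up to 0.190) and neurons without 1-day replicate 2 or 3 or 7-day replicate 1 or 2 (up to 0.167). The glucocorticoid list was not called without 1-day replicate 2 or 3 or 7-day replicate 2 (up to 0.382), nor with sex as a term (-0.14, 0.718). Between 7 and 14 days they were myelin without 7-day replicate 2 (0.777) or 14-day replicate 2 (0.601), macrophages without 7-day replicate 3 (median 0.09, adjusted p = 0.367) or 14-day replicate 3 (0.511), and neutrophils without 7-day replicate 3 (-0.25, 0.220), and the interferon median was -0.19 without 14-day replicate 2 (adjusted p = 4.16e-05).

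Other list medians between times moved by over 1.5 times and stayed called. For 7 days against 1 day the sex term gave -0.18 for immediate early genes, -0.08 for cytokines and -0.31 for the circadian clock. It also added calls of the unfolded protein response (median -0.14, adjusted p = 0.00141) and complement (-0.18, 0.0387), and between 7 and 14 days of heat shock (0.07, 0.0479) and cytokines (-0.09, 0.0469). For 7 days against 1 day the cytokine median was -0.06 and -0.28 without 1-day replicate 1 or 2 and -0.04 and -0.32 without 7-day replicate 1 or 2. Immediate early genes had -0.19 and -0.53 without 7-day replicate 2 or 3, and without the latter the antioxidant response had -0.27 and the circadian clock -0.32. Between 7 and 14 days cholesterol synthesis had -0.10 without 7-day replicate 2 and -0.11 and -0.02 without 14-day replicate 1 or 2, and myelin -0.10 without 7-day replicate 1 or 14-day replicate 3. The circadian clock had 0.20 without 7-day replicate 3 and 0.22 and 0.06 without 14-day replicate 1 or 3, and the interferon response 0.55 and 0.54 without the same 14-day arrays. Macrophage genes had -0.14 and -0.16 without 7-day replicate 1 or 2 and -0.12 without 14-day replicate 2.

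Other settings changed list calls between times too. With the lowest 50% of genes left out, the antioxidant (median -0.01, adjusted p = 0.0987) and complement lists (0.13, 0.491) were not called for 1 day against the immediate group, nor the node of Ranvier (0.0524), glucocorticoid (0.0816) and cytokine lists (0.02, 0.992) for 7 days against 1 day. The cell cycle medians were then 0.13 and -0.19 for these comparisons, and the neutrophil median between 7 and 14 days -1.43. Complement was also lost with array weights (0.0506), quantile normalization (0.0572) and a common 75th percentile (0.0518). The node of Ranvier list was lost for 7 days against 1 day as the mean over probe sets (0.119), with array weights (0.0731), a fit to the 2 groups (0.0519), a common 75th percentile (0.0579) and no eBayes trend (0.0624), the last of which also ended the neuron call (0.0624). Cytokine genes had -0.10 without the filter, -0.79 as the mean over probe sets and -0.11 with every probe set by itself. Every probe set by itself also gave 0.08 for the antioxidant response, -0.18 for the glucocorticoid response and, between 7 and 14 days, -0.03 for myelin. Between 7 and 14 days myelin was not called without the filter (0.0638), where neutrophils had -0.21, and macrophages had -0.11 with array weights. Female arrays gave -0.09 for myelin, -0.15 for macrophages, 0.62 for the interferon response and -0.67 for neutrophils.

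Signals also appeared in probe sets outside the comparisons. Of 9160 probe sets without a gene name 4 were higher than in controls immediately after noise and 8 at 1 day, with 2 lower each time, and of 932 with several genes 1 and 5 were higher and 1 and 0 lower. Between the immediate group and 1 day 44 of the unnamed sets rose and 65 fell, and 28 and 8 of those with several genes. From 1 to 7 days these counts were 53 and 84, and 9 and 35, and from 7 to 14 days all were 0. Of 64 control sets 1 fell at 1 day and 2 at 7 days against control, 1 rose and 3 fell from the immediate group to 1 day, and 2 fell from 1 to 7 days.

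The 434 genes called at 1 day compare male with female animals. With sex as a term 75 were called and all 434 kept their direction, with a median change of 0.42 before and 0.43 after the term, while the median standard error over all genes went from 0.097 to 0.129, so calls ended with the larger error. A sex difference as the whole cause would show in the same genes between males and females within the other 3 noise groups. There the median difference was -0.044 of the 1-day change (SE 0.068), near 0 where about 1 is needed. This cannot decide. The fit that chose the genes had no sex term, so a sex difference within those groups counted as spread and worked against a call. None of Xist, Tsix and the Y-linked genes was among the 434. The median of 0.43 with the term rests on the same within-group differences. RNA quality as read by the 3' minus 5' shift cannot be told apart. Group means at 1 and 7 days were 0.48 and 0.48 for beta-actin and -0.25 and -0.27 for Gapdh, though 1276 genes differed. In proportion to the shift, RNA quality would move the 434 genes at 7 and 14 days. There their change was 0.136 of that at 1 day (SE 0.041), and the controls shared by both changes can give a value above 0. The shift averaged -0.052 against -0.053 at 1 day for beta-actin and -0.053 against -0.033 for Gapdh. With all arrays both 3' minus 5' shifts lay beyond what so small a move allows. That of beta-actin did not with any of 8 of the 12 arrays left out, nor that of Gapdh without control replicate 1 or 3. The 5' set of 18S ribosomal RNA shifted by -0.773 at 7 and 14 days against -0.08 at 1 day. This lay beyond the same bound (-0.7559, where 0.2775 was needed). It argues against a cause of the 434 calls that follows this set, though no array was left out there. A response to noise, a sex difference, a sex difference in that response, or RNA quality as read by the 3' minus 5' shift stays open.

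The fall of Dbp and Ciart at 7 days could come from tissue taken at another hour than in the controls. Genes of the opposite clock phase, Arntl (0.56 ± 0.17), Npas2 (0.56 ± 0.35) and Clock (0.14 ± 0.09), had a mean change of 0.42 with a standard error of 0.22, just under 2 standard errors. The hour of collection and an effect of noise on the clock cannot be told apart with this value, as no collection time was used here. The 18S ribosomal RNA control sets at the 5' end (-0.91) and in the middle (-1.13) were lower on the same 7-day arrays, and whether this bears on Dbp and Ciart was not tested.

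The bone, neutrophil and erythroid lists were called lower at 7 and 14 days at the preset correlation, with 0 members called over all genes and only 4 erythroid genes tested. Bone genes were also called lower immediately (median -0.36) and at 1 day (-0.80). Without control replicate 3 these medians were -0.03, not called (adjusted p = 0.692), and -0.49, still called. The neutrophil and erythroid lists were not called at those earlier times. Arrays that carry different amounts of bone and marrow from the dissection may account for part of the falls of these lists, those of bone at the earlier times included. Whether the falls of the cartilage, tendon and muscle genes at 1 day have the same source was not tested. Bone and neutrophil scores, centred within groups, correlated over the 15 arrays (r = 0.86, exact within-group permutation p = 0.00772). Spearman's rho was 0.85 (p = 0.00604 by the same permutation). Without the 2 arrays farthest from the median r was 0.69. Scores were still centred with those 2 arrays, so this does not show the correlation without them. Correlations of bone with erythroid (r = 0.70) and neutrophil with erythroid scores (r = 0.76) are given as values. Control replicate 3 had the highest scores, 0.91 for bone against 0.12 and 0.14 in the other controls and 2.11 for neutrophils against -0.65 and 0.04. Without it the 7-day medians were 0.09 for neutrophils, -0.08 for erythroid genes (adjusted p = 0.728) and -0.15 for bone, none called, and at 14 days the erythroid call was lost (-0.10, 0.402) while neutrophils (-0.40) and bone (-0.23) were still called. A lower share of all non-neural cells cannot be told apart: at 14 days the change of the bone score minus that of endothelium was -0.48 and minus that of matrix genes -0.34, beyond the 0.46 and 0.28 needed, but -0.20 and -0.22 without control replicate 3, short of 0.30 and 0.27, and a change in marrow after noise stays open.

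Chance was tested by regrouping the arrays. Of 100 groupings of the 15 arrays, the real grouping included, 1 gave at least 921 genes by the F test, with 517 as the highest other. A random grouping would thus rarely give that count. The regroupings mixed the sexes, whereas all controls were female and all 1-day animals male. With sex as a term the real count was 435, for which no regrouping was run. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real splits gave 127, 434, 3, 1145 and 1276 genes for the immediate, 1-day and 7-day groups against control, 1 day against the immediate group and 7 days against 1 day, each with 0 as the highest other. At 14 days against control all 10 splits gave 0. Between 7 and 14 days the real split gave 0 and the highest other 24, for 14-day replicates 1 and 3 with 7-day replicate 2 against the rest. With 10 splits it cannot be told whether this is more than chance.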

How the results depend on the processing

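Female arrays alone were chosen as an alternative after the data were seen. Counts stayed within 1.5 times under no filter, the mean over probe sets, eBayes without the trend, robust eBayes, quantile normalization and a common 75th percentile. A similar count need not hold the same genes. The mean over probe sets kept 89 of the 127 immediate calls and 271 of the 434 at 1 day. The cause of the moves below was not tested unless fewer genes or arrays were used. Signal near background limits dim genes, only the lowest of which the filter removed, and 3 arrays per group limit all genes. No pseudocount was tried, as values were log2. With the dimmest 50% left out no erythroid gene remained. Female arrays cannot give the comparisons with 1 day, and fits to 2 groups or to females give no F test.

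Array weights gave 757 genes immediately after noise, 1106 at 1 day, 1 at 14 days, 1898 for 1 day against the immediate group, 710 for 7 days against 1 day, 1798 by the F test and an overlap of 128. Sex as a term gave 79, 75, 652 and 449 genes for the immediate and 1-day groups against control, 1 day against the immediate group and 7 days against 1 day, 435 by the F test and an overlap of 5. Every probe set by itself gave 246 genes immediately, 16 at 7 days, 1679 by the F test and 17 lists for 1 day against the immediate group. The filter of the lowest 50% gave 7 genes at 7 days, and fits to the 2 groups 1 at 7 days and 200 for 7 days against 1 day. An unadjusted p under 0.05 with 1.5-fold gave 195 genes at 1 day, 58 at 7 days, 58 at 14 days, 271 and 222 for the first 2 consecutive pairs and 7 between 7 and 14 days. Female arrays gave 8 genes immediately, and 7 lists at 7 days and 11 between 7 and 14 days. With an estimated correlation 0 lists were called in any of the 7 comparisons, and fry called 2, 3, 1 and 0 from the immediate group to 14 days, 7 for 1 day against the immediate group and 0 between 7 and 14 days.

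Some directions reversed. With the lowest 50% left out, the cytokine median was -0.16 immediately, -0.07 at 1 day and 0.02 for 7 days against 1 day. The mean over probe sets gave 0.02 for Qk immediately and 0.06 for Egr2 at 1 day. Array weights gave Mag 0.00 immediately and 0.05 at 1 day. Sex as a term gave Mbp -0.07, 0.00 and -0.01 at 1, 7 and 14 days, and Egr2 0.04 at 1 day. A common 75th percentile gave Mbp 0.00 at 1 day and -0.01 at 14 days. Female arrays gave Mag 0.05 immediately, and Qk 0.04 and Mbp -0.04 at 14 days. None of these genes was called in these fits, and the cytokine list was not called with the lowest 50% left out. Of the genes named as called, a fit to the 2 groups ended the calls of Junb, Socs3, Smpd3 and Btla immediately and Ibsp and Ncmap at 1 day, and robust eBayes those of Junb and Socs3 immediately, Fos, Ibsp and Dmp1 at 1 day and Kbtbd8 and Ptgs2 for 7 days against 1 day. EBayes without the trend ended those of Fos, Ibsp, Ncmap and Dmp1 at 1 day, Neat1 and Kbtbd8, the mean over probe sets those of Ccsap immediately, Ibsp, Ttn and Dmp1 at 1 day and Neat1, and array weights those of Neat1, Kbtbd8 and Ptgs2. Quantile normalization ended that of D930003E18Rik, a common 75th percentile that of Ccsap, no filter that of Kbtbd8, and fits to 2 groups also those of Neat1, Ciart and Kbtbd8. Female arrays ended 13 of the immediate calls, Fos (adjusted p = 0.0515), Nr4a3 (0.0567) and Fosl2 (0.0769) among them.

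Leaving out each of the 15 arrays gave 29 to 171 genes immediately, 112 to 582 at 1 day, 2 to 50 at 7 days and 0 to 1 at 14 days. It gave 382 to 1311 for 1 day against the immediate group, 429 to 1329 for 7 days against 1 day, 0 to 1 between 7 and 14 days, 307 to 1275 by the F test and an overlap of 5 to 33. Lists called ranged from 5 to 11 immediately (11 without control replicate 1), 4 to 14 at 7 days (4 without control replicate 3), 7 to 14 at 14 days (14 without 14-day replicate 2) and 6 to 11 between 7 and 14 days (11 without 7-day replicate 1 or 14-day replicate 1, 10 without 14-day replicate 2). Medians ranged from -1.44 to 0.09 for neutrophils at 7 days, the latter without control replicate 3. Between 7 and 14 days they ranged from -0.16 to 0.09 for macrophages, the latter without 7-day replicate 3, and from -0.19 to 0.55 for the interferon list, the former without 14-day replicate 2. Mag ranged from -0.18 to 0.08 immediately and -0.16 to 0.10 at 1 day, Egr2 from -0.16 to 0.15 at 1 day, and Mbp from -0.02 to 0.06, 0.00 to 0.08 and -0.04 to 0.06 at 1, 7 and 14 days. Qk ranged from -0.07 to 0.00 at 7 days and -0.08 to 0.04 at 14 days, and Pmp22 from -0.04 to 0.01 at 7 days.

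The replicate numbers were tested as a block. Arrays of the same number correlated from -0.33 to 0.30 over 30 pairs. The main fit left the numbers out, as some pairs lay under 0.1, though this does not rule pairing out. The mean was 0.052, against -0.026 for other numbers, and 9 of 15 arrays were closest to their own number. Whether that count exceeds chance was not tested, so pairing was neither shown nor excluded. The block gave 182 genes immediately and 567 at 1 day, against 127 and 434 without it, every count of calls within 1.5 times. Of the named genes D930003E18Rik was not called (adjusted p = 0.0506), nor were the lists of the circadian clock at 14 days (0.0607), complement for 1 day against the immediate group (0.0536) and the node of Ranvier for 7 days against 1 day (0.0516).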

Other observations

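The axon injury list was written after Atf3, Vgf and Gadd45a had been seen, and the genes named in this part were chosen after their values were seen.

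Further genes of the immediate and 1-day responses passed the test. Immediately after noise the transcription factor gene Maff rose by 1.38 ± 0.20, the phosphatase gene Dusp1, which turns off kinase signalling, by 1.24 ± 0.22, Btg2 by 1.17 ± 0.25 and the chaperone gene Hspa8 by 0.34 ± 0.06. At 1 day Timp1, an inhibitor of matrix proteases, rose by 1.48 ± 0.23, the monocyte-attracting chemokine genes Ccl2 by 1.15 ± 0.28 and Ccl7 by 0.94 ± 0.21 (control means of 4.53 and 4.48, under the filter level, leave these sizes uncertain), and the complement genes C1qa by 0.88 ± 0.19 and C1qc by 1.04 ± 0.17. With sex as a term Timp1 was called (adjusted p = 0.0428), and Ccl2 (0.335), Ccl7 (0.298), C1qa (0.149) and C1qc (0.0724) were not. The clock gene Per2 rose by 0.56 ± 0.11 at 1 day (adjusted p = 0.0161), and differed by -0.49 ± 0.11 at 7 days, which did not pass (adjusted p = 0.173). Its change from 1 to 7 days, -1.05 ± 0.11, did pass (adjusted p = 0.000556).

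The transferrin receptor gene Tfrc stood at 11.60 in controls and 10.75 at 1 day, given as values. Its control set at the 5' end fell by 0.94 ± 0.17 on the log2 scale (adjusted p = 0.0282), while those at the 3' end (-0.62, adjusted p = 0.0828) and in the middle (-0.68, adjusted p = 0.0574) did not pass. The 5' set differed by -0.85 at 7 days (adjusted p = 0.103) and -0.83 at 14 days (adjusted p = 0.342), which did not pass, so the fall was not shown to be particular to 1 day.

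A hypothesis was that neurons of the nerve show an axon injury response at 1 day, as Atf3, Vgf and Gadd45a rose. A list of 25 other genes of that response, 18 of them tested, had a median of 0.20 at 1 day, where camera gave 0.0436 before adjustment and an adjusted p = 0.12 over the 7 comparisons, which did not pass. With an estimated correlation the unadjusted value was 0.20. Such a response may exist, but the evidence is weak: 11 of 18 were higher, and 0 passed with limma over all genes or adjusted over the list alone, where 1 of 18 passed immediately after noise. Values of 0.0487 immediately after noise and 0.0515 at 7 days, before adjustment, lay close to that at 1 day, so the shift was not particular to 1 day, and the highest changes at 1 day, Stmn4 (0.56 ± 0.18, adjusted p = 0.106) and Tnfrsf12a (0.54 ± 0.17, adjusted p = 0.0924), did not pass.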
